A study of Oryctolagus cuniculus with 36 samples.

How the data were processed

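RNA was profiled in 36 rabbit libraries, 6 in each of 6 groups: terminal ileum, the non-embolized caudal liver lobe and the embolized cranial liver lobe, each after obeticholic acid or vehicle. Per the labels' protocols, total RNA was made into strand-specific libraries and sequenced as paired-end reads of 150 bases. Per the submitters' processing notes, STAR, RSEM and DESeq2 were used; their versions, the genome build and the annotation are not given in the sources used here.

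The deposited values are a normalized signal, gene counts that the authors had divided by 1 size factor per library, in 1 table for the 12 ileum libraries and 1 for the 24 liver libraries. Both tables list the same 9419 Ensembl gene IDs. Every value was checked against the smallest step of its library: 100% of the values of each table were whole multiples of that step within a tolerance of 0.01, so the reads behind each value could be recovered. The 2 tables were normalized separately, so tests were made only within a table, and levels in ileum and liver are not on one scale.

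The files pair no gene ID with a name. The RefSeq gene table used here (assembly mOryCun1.1, 38822 genes) gives an Ensembl ID for 0 of its genes, so no match of the 9419 IDs was possible and genes appear under their IDs. The 38 gene lists fixed before the data were examined, among them bile acid, cell cycle and cell type lists, were therefore not tested, and checks of GC content and gene length were void because no ID had a value. The rule for genes named in the text had asked for bile acid genes and for the 8 largest rises and falls among genes with a symbol. It was adapted after the files were seen: for each comparison, the 2 largest rises and the 2 largest falls past the threshold with a mean normalized count of at least 50, and, where fewer than 5 genes passed, the 2 of lowest p in each direction. The IDs it gave for the interaction are not printed. In the comparison that picked them, such genes tend to have groups that do not overlap, so a lack of overlap is description and not added support.

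Recovered reads per library, in M (megareads), ranged from 11.2 M to 24.5 M in ileum and from 12 M to 27.3 M in liver. The 90 pairs of libraries within groups were compared by a chi-square of their reads; the smallest value per degree of freedom was 41.1, so no pair agreed within sampling noise. The labels do not say whether each library of a group came from a separate rabbit, so p-values measure only the spread between these libraries, which may be technical.

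The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(normalized count + 1), for genes with a normalized count of at least 10 in at least 6 libraries of the table, which left 9010 genes in ileum and 8653 in liver. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The 24 liver libraries were fitted together as 4 group means with a shared spread, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were obeticholic acid against vehicle in each of the 3 tissues, embolized against non-embolized lobe under each treatment, and the interaction of treatment and lobe. Errors beside group means are SDs over 6 libraries, and errors beside log2 fold changes are standard errors.

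The test was checked on simulated reads with 200 changed genes, all with a mean normalized count of at least 50. In the ileum comparison it recovered 22% of 2-fold and 74% of 4-fold changes. In the obeticholic acid comparisons it recovered 69% and 99% in the non-embolized lobe and 76% and 96% in the embolized lobe. Between lobes it recovered 69% and 95% under vehicle and 70% and 97% under obeticholic acid, where 6.18% of calls were false, the highest share of the 5 comparisons simulated. Recovery of lower genes was not simulated. The simulated genes varied independently, so the shares of false calls leave out any structure shared between genes of these libraries.

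Replicate numbers were tested as possible pairs by correlating deviations from group means across genes. Between the vehicle lobes all 6 correlations of same-numbered libraries exceeded 0.1 (0.14 to 0.53), and 4 of the 6 matched best with their own number. These numbers were therefore read as pairs, from the data and not from a label. That reading is an assumption. Between vehicle and obeticholic acid libraries of the non-embolized lobe 4 of 6 also exceeded 0.1, up to 0.54, and 2 matched best with their own number. Such correlations can thus arise between libraries of different treatment. Between the obeticholic acid lobes 5 of 6 exceeded 0.1, which leaves pairing open, and the numbers were not read as pairs.

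Alternatives chosen before the data were examined were 2 other scalings (equal totals, equal upper quartiles), pseudocounts of 0.5 and 5, other filters, no variance trend, sample quality weights, a replicate block, a term for replicates 1 to 3 against 4 to 6 (which follow 2 runs of library numbers), a fit of only the groups compared, and each library left out in turn. Chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, reads thinned to equal depth, fits within replicates 1 to 3 and 4 to 6, and fits without libraries that stood apart.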

Results

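Portal vein embolization blocks the portal branches that feed part of the liver; the blocked lobes shrink and the others grow. Rabbits received vehicle or obeticholic acid, a bile acid derivative that activates the nuclear receptor FXR, before embolization. Transcripts were measured in the terminal ileum, the non-embolized caudal lobe, which the labels call hypertrophic, and the embolized cranial lobe, which they call atrophic, with 6 libraries per treatment in each. Recovered reads, in M (megareads), averaged 17.5 ± 4.04 M (SD, n = 6) in ileum after vehicle and 14.4 ± 2.76 M after obeticholic acid. The non-embolized lobe had 20.3 ± 4.38 M after vehicle and 19.5 ± 4.67 M after obeticholic acid, and the embolized lobe 13.8 ± 1.22 M and 14.7 ± 2.15 M. The first principal component of the liver libraries held 36.5% of their variance and separated the lobes; in ileum, vehicle 6 and obeticholic acid 1 lay apart from the other 10 libraries.

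**Figure D1:**
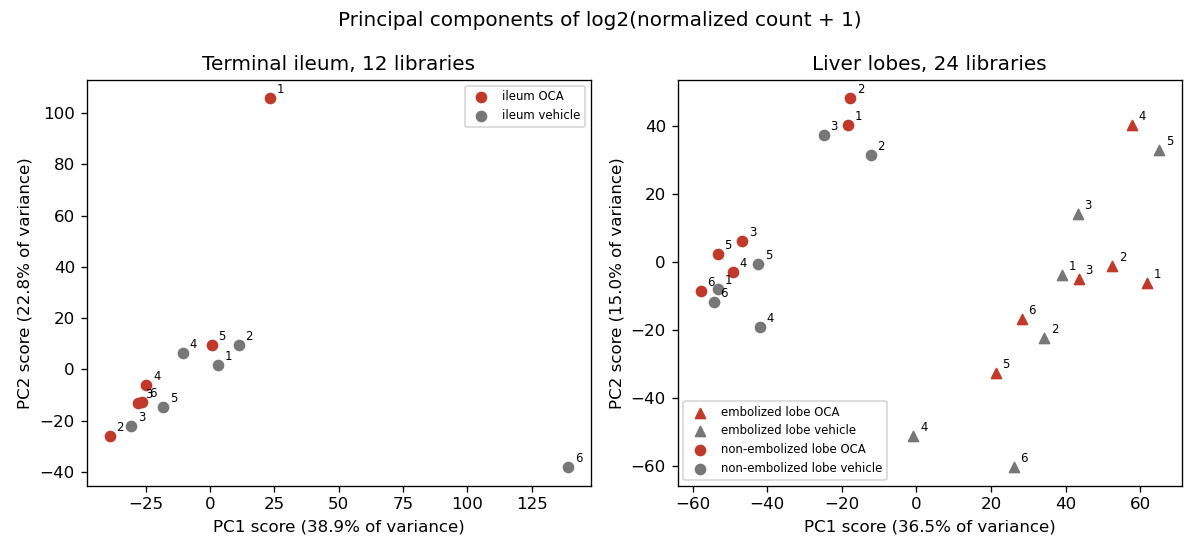
Scores of each library on the first 2 principal components of log2(normalized count + 1), with the share of variance on each axis and the replicate number beside each point; grey is vehicle, red is obeticholic acid (OCA), and triangles are embolized lobes. In liver, PC1 (36.5%) parts the lobes; in ileum, vehicle 6 lies alone on PC1 (38.9%) and OCA 1 on PC2 (22.8%).

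The embolized and non-embolized lobes of vehicle animals were compared first. The embolized lobe was always cranial and the non-embolized lobe always caudal, so embolization and lobe position cannot be told apart in these comparisons. In the embolized lobe 1010 genes were higher and 1200 lower, of 8653 tested, with 474 and 506 of them changed at least 2-fold. Genes higher in the embolized lobe took 9.74 ± 0.86% of the reads in the non-embolized lobe and 17.4 ± 1.27% in the embolized lobe (SD, n = 6). Genes lower there took 11.4 ± 0.46% and 5.62 ± 1.10%. These shares describe the called genes and are not a separate test. ENSOCUG00000005666 averaged 3667 ± 1121 normalized counts in the non-embolized lobe and 141 ± 112 in the embolized lobe (log2 fold change −5.28 ± 0.52, limma adjusted p = 2.87e-07), with no overlap between the groups. ENSOCUG00000010723 averaged 106 ± 64.6 and 1.84 ± 4.50 (−5.89 ± 0.66, limma adjusted p = 9.51e-07); it was at 0 in 5 of the 6 embolized libraries. ENSOCUG00000007265 rose from 2.00 ± 1.47 to 280 ± 495 (4.38 ± 1.00, limma adjusted p = 0.00221). ENSOCUG00000010247 was at 0 in 5 of the 6 non-embolized libraries and at 0.522 in the other, and in the embolized lobe it ran from 0 in vehicle 2 and 4 to 739 in vehicle 5 (limma adjusted p = 0.00714). ENSOCUG00000007265 was likewise lowest in embolized vehicle 2 and 4 (2.95 and 5.90) and highest in vehicle 5 (1276), so both rises rested on the same libraries. The log2 fold change of ENSOCUG00000007265 was 5.15 without embolized vehicle 2, 4.99 without vehicle 4 and 3.49 without vehicle 5, that of ENSOCUG00000005666 was −4.68 without vehicle 2, and that of ENSOCUG00000010723 was −6.49 without vehicle 3. Across all other settings ENSOCUG00000007265 ran from 3.37 to 7.13, ENSOCUG00000010247 from 3.18 to 9.65, ENSOCUG00000010723 from −6.73 to −3.96 and ENSOCUG00000005666 from −5.67 to −4.68. Scaling to equal totals gave 616 higher and 1304 lower, sample quality weights gave 1714 and 1729, and within replicates 1 to 3 and 4 to 6 there were 1134 and 579 calls.

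The same lobes were compared after obeticholic acid. Here 1428 genes were higher and 1353 lower in the embolized lobe, 810 and 453 of them at least 2-fold. Higher genes took 10.8 ± 1.15% of reads in the non-embolized and 21.6 ± 1.80% in the embolized lobe, and lower genes 16.5 ± 0.90% and 9.21 ± 0.98% (SD, n = 6). ENSOCUG00000008303 rose from 3.13 ± 3.55 to 1358 ± 1183 normalized counts (log2 fold change 8.40 ± 1.20, limma adjusted p = 1.46e-05). ENSOCUG00000022536 was between 7.62 and 52.6 in the non-embolized and between 410 and 42347 in the embolized lobe (8.34 ± 1.74, limma adjusted p = 0.000749), so its SD of 16775 exceeded its mean of 13311. ENSOCUG00000010723 fell from 1026 ± 289 to 17.4 ± 16.8 (−6.42 ± 0.66, limma adjusted p = 3.74e-07), and ENSOCUG00000001012 from 199.7 ± 86.4 to 17.6 ± 12 (−3.88 ± 0.85, limma adjusted p = 0.00123). The log2 fold change of ENSOCUG00000022536 was 9.04 without embolized obeticholic acid 3 and 7.70 without obeticholic acid 4, and that of ENSOCUG00000001012 was −3.16 without obeticholic acid 1. ENSOCUG00000001012 lost its call within replicates 4 to 6 (limma adjusted p = 0.0976). Within replicates 1 to 3 there were 2083 calls, 1056 higher and 1027 lower. Within replicates 4 to 6 there were 834, and the balance turned, with 396 higher and 438 lower. Equal upper quartiles gave 1649 higher and 1203 lower.

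Between the treatments, 689 genes were higher in the embolized lobe in both comparisons, where independent lists would share 166.7, and 879 were lower in both, where they would share 187.6. No gene was called in opposite directions. Across the 8653 genes, which are not independent replicates, the log2 fold changes of the lobe comparisons correlated at r = 0.84; the 2 comparisons share no library.

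**Figure D2:**
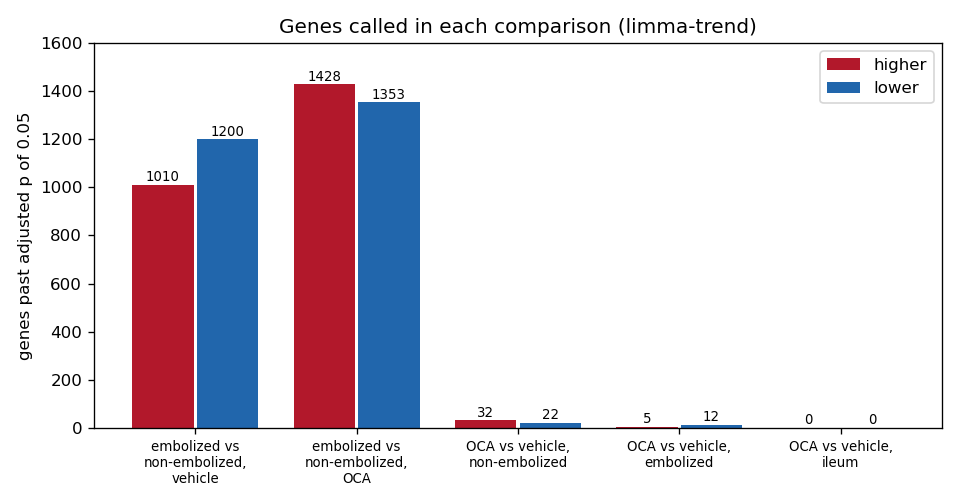
Number of genes past an adjusted p of 0.05 (limma-trend) in each comparison, red for higher and blue for lower in the first-named condition. The lobes differed by 2210 genes under vehicle and 2781 under obeticholic acid (OCA), and OCA against vehicle gave 54, 17 and 0 genes in the non-embolized lobe, embolized lobe and ileum.

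Obeticholic acid was compared with vehicle in the non-embolized lobe, the lobe that grows. It raised 32 genes and lowered 22, with a median size of 0.91 on the log2 scale; 9 rose and 12 fell at least 2-fold. ENSOCUG00000010723, which was also lower in the embolized than in the non-embolized lobe, averaged 106 ± 64.6 normalized counts after vehicle and 1026 ± 289 after obeticholic acid (SD, n = 6; log2 fold change 3.47 ± 0.66, limma adjusted p = 0.0188). ENSOCUG00000012661 rose from 9.91 ± 6.51 to 97.2 ± 46.1 (3.23 ± 0.38, limma adjusted p = 7.85e-05). In both, every treated library lay above every vehicle library. In the embolized lobe both also rose without passing, by 2.94 ± 0.66 (limma adjusted p = 0.0522) and 1.49 ± 0.38 (limma adjusted p = 0.0997) on the log2 scale. ENSOCUG00000024137 fell from 103 ± 23 to 29.2 ± 32.8 (−2.53 ± 0.60, limma adjusted p = 0.0473) and ENSOCUG00000001920 from 104 ± 38.6 to 35.9 ± 19.1 (−1.59 ± 0.37, limma adjusted p = 0.0433). Each of these 2 falls lost its call in 10 of the 12 fits that left out 1 library, with an adjusted p of up to 0.126 for ENSOCUG00000024137 and 0.127 for ENSOCUG00000001920. In such fits ENSOCUG00000010723 lost its call without obeticholic acid 4 (0.0522). Over all 28 other settings, these fits included, ENSOCUG00000024137 lost its call in 18 (log2 fold change −2.94 to −1.85) and ENSOCUG00000001920 in 16 (−2.17 to −1.01). Within replicates 1 to 3 none of the 4 genes passed (limma adjusted p 0.207 to 0.732), and within 4 to 6 only the 2 rises did.

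The number of genes called in the non-embolized lobe rested on single libraries: it was 112 without vehicle 3, 18 without vehicle 4, 12 without vehicle 5, 9 without vehicle 6, 10 without obeticholic acid 4, 33 without obeticholic acid 5 and 26 without obeticholic acid 6. Within replicates 1 to 3 and 4 to 6 there were 5 and 26 calls. Equal totals gave 15 higher and 14 lower genes, sample quality weights 211 and 187, and DESeq2 on the recovered reads 146 and 119. Without obeticholic acid 3 there were 30 higher and 37 lower. The term for replicates 1 to 3 against 4 to 6 and the replicate block each called more genes than the main fit.

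In the embolized lobe obeticholic acid raised 5 genes and lowered 12, with a median size of 1.24 on the log2 scale. ENSOCUG00000024104 rose from 40.1 ± 31.1 to 363 ± 292 normalized counts (SD, n = 6; log2 fold change 3.08 ± 0.47, limma adjusted p = 0.00723). ENSOCUG00000005666, which was far lower in the embolized than in the non-embolized lobe, rose from 141 ± 112 to 788 ± 357 (2.99 ± 0.52, limma adjusted p = 0.0111). In the non-embolized lobe it was at 3667 ± 1121 after vehicle and 6583 ± 735 after obeticholic acid, without overlap between the groups (0.90 ± 0.52, limma adjusted p = 0.476). This standard error is shared by all liver groups, and the embolized vehicle libraries ran from 10.3 to 266. The p thus does not show that the gene failed to respond in the non-embolized lobe. ENSOCUG00000012283 fell from 3989 ± 1750 to 543 ± 566 (−3.94 ± 0.72, limma adjusted p = 0.0126), and ENSOCUG00000003569 from 1218 ± 740 to 269.8 ± 43.4 (−1.91 ± 0.38, limma adjusted p = 0.0301). Both also fell in the non-embolized lobe without passing. There ENSOCUG00000012283 went from 2211 ± 1101 to 342 ± 198 without overlap (−2.71 ± 0.72, limma adjusted p = 0.0785), and ENSOCUG00000003569 changed by −1.02 ± 0.38 (limma adjusted p = 0.208). ENSOCUG00000003569 lost its call in 8 of 12 fits that left out 1 library (adjusted p up to 0.117). None of these 4 genes passed when only the 2 groups were fitted (up to 0.259). Within replicates 1 to 3 only ENSOCUG00000003569 passed, within 4 to 6 only ENSOCUG00000005666, and with edgeR ENSOCUG00000012283 did not (adjusted p = 0.0628). The log2 fold change of ENSOCUG00000005666 was 2.39 without vehicle 2, and that of ENSOCUG00000012283 was −3.19 without obeticholic acid 2.

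The direction of the calls in the embolized lobe moved with the scaling and with the libraries fitted. Equal totals gave 9 higher and 5 lower genes and shifted the median of all genes to 0.15 on the log2 scale; equal upper quartiles gave 7 and 9. The count was 9 without vehicle 1, 9 without vehicle 2, 38 without vehicle 3, 11 without vehicle 4, 294 without vehicle 5, 28 without vehicle 6, 8 without obeticholic acid 2, 39 without obeticholic acid 3, 11 without obeticholic acid 5 and 9 without obeticholic acid 6. It was 0 when only these 12 libraries were fitted, and within replicates 1 to 3 and 4 to 6 there were 4 higher and 1 lower, and 3 higher and 0 lower. Sample quality weights gave 52 higher and 53 lower genes, DESeq2 24 and 68, and a pseudocount of 5 gave 10 and 17.

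**Figure D3:**
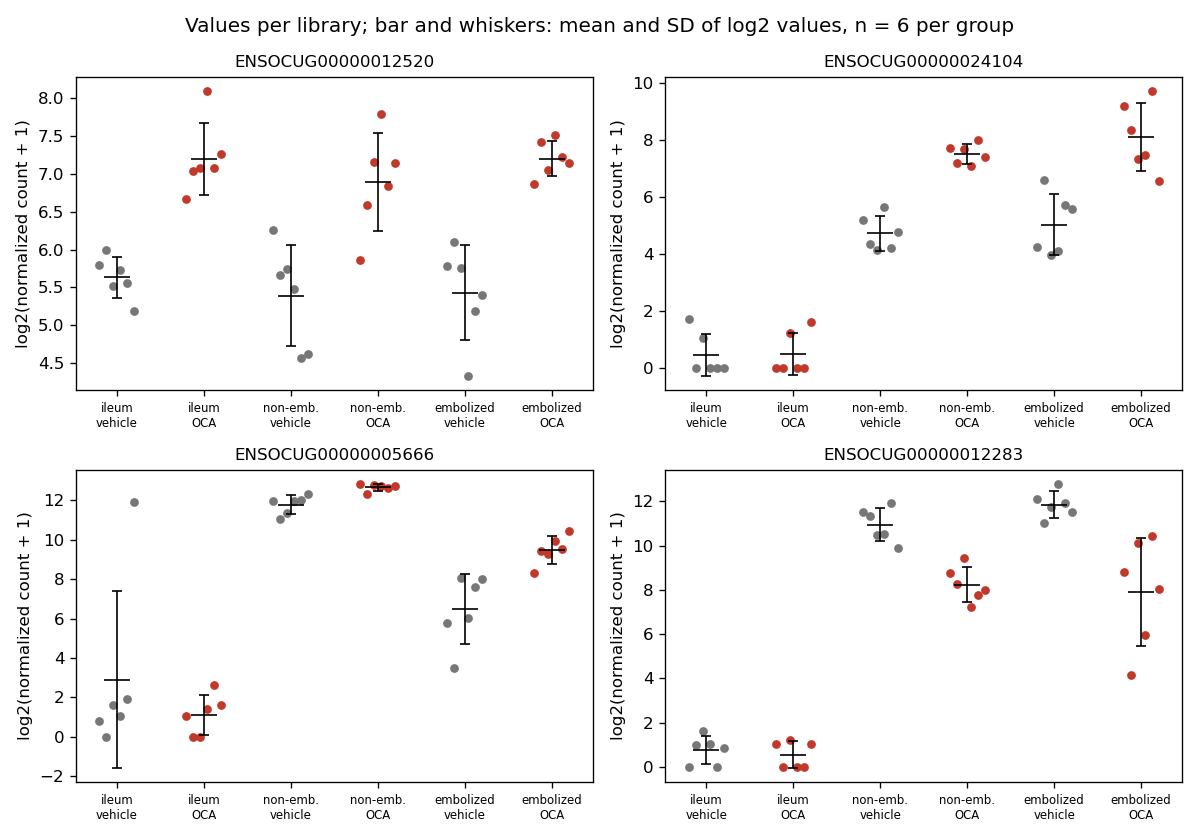
Values of 4 genes per library as log2(normalized count + 1) in the 6 groups (grey vehicle, red obeticholic acid), with the mean and SD of the log2 values, n = 6 per group. ENSOCUG00000012520 and ENSOCUG00000024104 rose in both lobes. ENSOCUG00000005666 and ENSOCUG00000012283 passed the test in the embolized lobe and moved the same way in the non-embolized lobe without passing. Ileum and liver were normalized separately, so their levels are not on one scale.

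Genes that answered obeticholic acid were compared between the lobes. Called genes higher in both lobes numbered 3, where independent lists would share 0.0185 (Fisher's exact test, one-sided p = 4.57e-07), and 0 were lower in both, where they would share 0.0305. These expected counts and this p treat the lobes as independent, although they may come from the same animals. Both comparisons also came from 1 fit with a shared spread, which favours genes of small spread in both lists. When the 12 replicate numbers were split at random, keeping both lobes of a number together, 1 of 100 splits, the real one, gave 3 shared genes, and the highest other gave 2. The 3 genes, named after their values were seen, were ENSOCUG00000006639 (log2 fold change 0.96 in the non-embolized and 0.90 in the embolized lobe), ENSOCUG00000012520 (1.51 and 1.77) and ENSOCUG00000024104 (2.80 and 3.08). Of the 54 genes called in the non-embolized lobe 45 had the same sign in the embolized lobe, and of the 17 called in the embolized lobe all 17 had the same sign in the other. In the random splits a median of 42 of the 54 and 14 of the 17 genes of lowest p had the same sign, and 41 and 11 of 100 splits, the real one included, gave as many as observed. The overlap was 1 gene without non-embolized vehicle 5, without vehicle 6 and without obeticholic acid 4, and 8 genes without embolized vehicle 5. It was 0 when only the groups compared were fitted. Sample quality weights, DESeq2, a replicate block and a term for the 2 runs of replicate numbers each gave more shared genes than the main fit.

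The interaction asked whether the response to obeticholic acid differed between the lobes. No gene passed (limma-trend, smallest adjusted p = 0.561). At an unadjusted p under 0.05 there were 631 genes, where 432.65 would be expected with no effect. Genes vary together and this count was not set against random splits, so the excess is not evidence of a difference. With edgeR 0 genes were called and with DESeq2 5. For ENSOCUG00000005666 the response in the embolized lobe exceeded that in the non-embolized lobe by 2.09 ± 0.73 on the log2 scale (limma adjusted p = 0.607), so its call in 1 lobe was not shown to differ from the other.

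In the terminal ileum, where bile acids are taken back up, no gene passed the threshold after obeticholic acid (limma-trend, smallest adjusted p = 0.234). At an unadjusted p under 0.05 there were 688 genes, where 450.5 would be expected with no effect. Genes vary together, so such counts can lie far from that expected by chance. The term for replicates 1 to 3 against 4 to 6 gave 105 in the same libraries. The excess was not set against random splits. On the recovered reads edgeR called 0 genes, with 973 at an unadjusted p under 0.05, and DESeq2 called 80 (47 higher, 33 lower), with 1016. Among genes that did not pass, ENSOCUG00000012520, which rose in both lobes, was at 49.3 ± 9.37 normalized counts after vehicle and 153.6 ± 60.2 after obeticholic acid (SD, n = 6; log2 fold change 1.57 ± 0.25), and ENSOCUG00000010659 was at 28.4 ± 6.32 and 73.1 ± 15.3 (1.34 ± 0.24). ENSOCUG00000009455 was at 676 ± 139 and 314 ± 67.3 (−1.11 ± 0.19), and ENSOCUG00000008560 at 17132 ± 4388 and 6263 ± 2213 (−1.50 ± 0.27). In each of these 4 genes the groups did not overlap, which is likely for genes picked for the lowest p and is no added evidence. Each had a limma adjusted p of 0.234 (edgeR 0.194). All 4 passed with DESeq2, at an adjusted p between 1.2e-05 and 0.000167, and in limma with sample quality weights, at 0.0138 to 0.0251. A fit with sample quality weights called 349 genes, and a fit without vehicle 6 and obeticholic acid 1, which lay apart, called 7, among them ENSOCUG00000012520 (limma adjusted p = 0.0452).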

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

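The test of ileum vehicle 6 and obeticholic acid 1 against a few dominant genes was chosen after the result had been seen.

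Vehicle 6 and obeticholic acid 1 lay apart in ileum. In vehicle 6 a single gene, ENSOCUG00000013891, took 27.7% of the reads, against 2.82 to 6.35% for the most abundant gene of the other vehicle libraries. In vehicle 6, 2817 genes lay over 2-fold from the median of the other vehicle libraries, and in obeticholic acid 1 there were 3442 in its group. The smaller of the 2 excesses over the next library was 2.35 times, and 2.27 times with reads thinned to equal depth, so depth does not account for them. Both libraries were picked for lying apart across all genes, so many shifted genes were likely from the outset. The test against a few dominant genes therefore decides little, and the top gene of obeticholic acid 1 took 3.36% of its reads. RNA from liver as the whole cause would raise the abundant liver-enriched genes together, but 13 of 50 lay over 2-fold above the group in vehicle 6 and 9 of 50 in obeticholic acid 1, while another vehicle library had 37; ENSOCUG00000005666, abundant in liver, was at 3934 in vehicle 6 and at most 5.18 in the other ileum libraries. Liver-enriched genes took 0.627% of the reads in vehicle 6, against 0.205 to 0.425% in the other 11 ileum libraries, so a small share of liver RNA there stays open. In the non-embolized vehicle lobe these genes took 48.0 to 55.1%, and ENSOCUG00000005666 averaged 3667, on a separate scale. A share that small would therefore not by itself give the 3934 of this gene in vehicle 6. Material of another kind in the sample remains a candidate explanation. In vehicle 6 there were 13 genes, and in obeticholic acid 1 there were 9, at 100 or more while under 10 in every other ileum library. Any other library held at most 1. They took only 0.161% and 0.0588% of the reads, and libraries picked for lying apart were likely to hold some. The genes named as higher in the embolized than the non-embolized lobe were also highest, in ileum, in obeticholic acid 1: ENSOCUG00000022536 at 3796 (at most 557 elsewhere in ileum), ENSOCUG00000008303 at 1246 (10.8), ENSOCUG00000010247 at 419 (32.8) and ENSOCUG00000007265 at 233 (118). No biological explanation was tested.

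Among 49 groups of values tested for a library far from the other 5, 5 held one. Chance gives about 1 in 20 groups, or 2.45 of 49. Gene values were tested as log2(normalized count + 1) and are printed here as counts. The groups did not take in every named gene in every tissue (ENSOCUG00000008303 in ileum was left out), so other such libraries may exist. In the first 2 genes that follow the other 5 values were 0, so any value above 0 stands out and that rate does not apply. Besides the gene above, ENSOCUG00000010247 was at 0.522 in non-embolized vehicle 3 and 0 in the other 5. ENSOCUG00000010723 was at 11 in embolized vehicle 3 and 0 in the others. ENSOCUG00000022536 was at 52.6 in non-embolized obeticholic acid 6, against 7.62 to 15.2 in the others. ENSOCUG00000001012 was at 0 in embolized obeticholic acid 1, against 10.2 to 31.3.

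Liver libraries of replicates 1 to 3 differed from those of replicates 4 to 6 in 651 genes (326 higher, 325 lower). The labels do not explain this division. In ileum the same term called 0 genes by limma. There 105 genes had an unadjusted p under 0.05, fewer than the 450.5 expected with no effect. With a count below that expected, the 0 does not show that ileum lacked such a division. In liver, 2 of 100 divisions of the same kind gave as many genes, the real one included, and the highest other gave 1258. Chance division is thus argued against there, but the libraries also differ along another line. With reads thinned to equal depth 603 genes were called, which argues against depth. A difference in handling between the 2 runs of libraries or between the animals may account for it; no label gives a date or batch, and neither was tested.

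Genes called in each comparison were set against random splits of the same libraries. Between the lobes 1 of 100 splits, the real one, reached the count under vehicle (2210 genes, highest other 620) and 1 of 100 under obeticholic acid (2781, highest other 1554). Among the 32 splits that part all vehicle pairs, 1 reached 2210, and the highest other gave 590. For obeticholic acid in the non-embolized lobe 2 of 100 splits reached 54 genes (highest other 124), and in the embolized lobe 3 of 100 reached 17. The highest other there gave 507 genes, several times the real count, which points to a structure of the samples. That split put vehicle 5 and obeticholic acid 4 on 1 side; across treatments their deviations from the group means correlated most closely (0.59 across genes, next 0.45). In ileum and for the interaction, where 0 genes were called, every split gives as many whatever the data hold (100 of 100, highest other 1 and 0), so the splits decide nothing. The 349 genes called in ileum with sample quality weights were reached by 11 of 100 splits (highest other 2213), so chance is not excluded there.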

How the results depend on the processing

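Of the counts of called genes, 82 values under other settings lay within 1.5 times the main count and 30 did not. With 1 library left out, 87 did and 21 did not. These tallies include ileum and the interaction, where 0 against 0 counted as within. All 21 concerned obeticholic acid in the lobes or the calls shared by both lobes. No named gene changed sign; the balance of higher and lower calls for obeticholic acid did turn. In the embolized lobe it turned with equal totals (9 and 5), without vehicle 5 (190 and 104), without vehicle 5 and obeticholic acid 4 (67 and 37) and within replicates 1 to 3 (4 and 1) and 4 to 6 (3 and 0). In the non-embolized lobe it turned without obeticholic acid 3 (30 and 37). Between the lobes under obeticholic acid it turned within replicates 4 to 6 (396 and 438). For single genes 334 values kept their side of the threshold, 29 lost it and 12 gained it, and with 1 library left out 307 kept it and 29 lost it. The tests on reads, thinning, the fits within replicate sets and the fits without libraries that stood apart were chosen after seeing the data, and the cause of a changed count was not tested except where stated.

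Sample quality weights called 349 genes in ileum, 398 in the non-embolized lobe, 105 in the embolized lobe, 3443 between vehicle lobes and 17 shared by the obeticholic acid calls of both lobes. DESeq2 called 80, 265 and 92 in the 3 tissues, 5 for the interaction and 21 shared. The term for replicates 1 to 3 against 4 to 6 gave 113 in the non-embolized lobe, 38 in the embolized lobe and 7 shared. Fitting only replicates 1 to 3, with fewer libraries, gave 5 in each lobe and 1134 between vehicle lobes; only replicates 4 to 6 gave 26 in the non-embolized and 3 in the embolized lobe, 579 and 834 between lobes under vehicle and obeticholic acid, and 1 shared. Equal totals gave 29 in the non-embolized lobe, a pseudocount of 5 gave 27 in the embolized lobe, and fitting only the groups compared gave 0 there and 0 shared. Without vehicle 6 and obeticholic acid 1 ileum gave 7, and without vehicle 5 and obeticholic acid 4 the embolized lobe gave 104.

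With a replicate block the counts were 127 and 30 for obeticholic acid in the non-embolized and embolized lobes, 11 shared, 2792 and 3317 between lobes under vehicle and obeticholic acid, and 0 in ileum and for the interaction. Numbers did not pair libraries across treatments (correlations −0.41 to 0.25 in ileum, −0.32 to 0.54 and −0.43 to 0.24 in the lobes). Between obeticholic acid lobes 5 of 6 correlations exceeded 0.1 (−0.11 to 0.49, 3 of 6 best with their own number), which leaves their pairing open. Between the vehicle lobes, whose numbers were read as pairs, the block moved the count from 2210 to 2792.

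With 1 library left out in turn, counts ran from 0 to 0 in ileum, 9 to 112 in the non-embolized and 8 to 294 in the embolized lobe, 1798 to 2609 and 2295 to 2754 between lobes under vehicle and obeticholic acid, 0 to 0 for the interaction and 1 to 8 shared. Equal totals moved the median of all genes in the interaction from 0.01 to 0.14. Depth limits genes near 0, where a step of 1 read is large.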

Other observations

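Lists of genes with at least 8-fold more reads in one tissue were drawn from these libraries after seeing the data, so they are not independent of them: 304 liver-enriched and 965 ileum-enriched genes, 698 of the latter measured in liver. Between the lobes, 148 ileum-enriched genes were higher and 50 lower in the embolized lobe under vehicle, with a median log2 fold change of 0.35, and 231 were higher and 47 lower under obeticholic acid, with a median of 0.58. Camera gave an adjusted p of 0.000241 and 1.15e-07 with a preset correlation, and an adjusted p = 0.492 in both with an estimated correlation. Liver-enriched genes split between higher and lower, 49 and 65 under vehicle and 51 and 68 under obeticholic acid. After obeticholic acid the liver-enriched median was −0.17 in the non-embolized and −0.23 in the embolized lobe, and the ileum-enriched median −0.01 and 0.24. With a preset correlation camera gave an adjusted p of 0.000185 and 4.6e-08 for the liver-enriched list and 0.923 and 0.000231 for the ileum-enriched list, and with an estimated correlation 0.492 in both lobes and 0.979 and 0.492.

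A shift in cell makeup of the embolized lobe may raise such genes, as a hypothesis that the unnamed genes leave without a marker test. The expression level of the listed genes does not account for the shift: the list's medians lay at percentile 100 of 10000 random lists matched on mean expression under both treatments (95% of these lay between 0.04 and 0.15 under vehicle and between 0.05 and 0.17 under obeticholic acid). With thinned reads the median, less that of all genes, kept 0.972 of its value. The same measure under other scalings, 0.971, decides nothing, because subtracting the median of all genes removes any factor per library. The list's mean per library differed between lobes by 0.49 under vehicle and 0.74 under obeticholic acid, with exact two-sided permutation p-values of 0.0368 and 0.00216, the latter the smallest possible. With the vehicle numbers read as pairs, 4 of 6 pairs were higher and 2 lower in the embolized lobe (exact sign-flip p = 0.125). Under vehicle the shift thus did not exceed the spread between pairs, but this rests on an assumed pairing, and the unpaired permutation p was 0.0368. Under obeticholic acid the shift exceeded the spread between libraries in the unpaired permutation test, while the p with an estimated correlation leaves it open. The obeticholic acid numbers were not read as pairs. If they were, 6 of 6 pairs were higher in the embolized lobe (exact sign-flip p = 0.0313, the smallest possible). The treatments were thus judged by different tests. These tests per library were chosen after the list's shares per library and its p with an estimated correlation had been seen; as a share of reads, ileum-enriched genes averaged 0.749 ± 0.0662% in the non-embolized and 0.757 ± 0.331% in the embolized lobe under vehicle, and 0.759 ± 0.129% and 0.868 ± 0.244% under obeticholic acid (SD, n = 6). Embolized vehicle 5 and obeticholic acid 4 had the highest shares in liver, 1.37% and 1.33%, and embolized vehicle 2, 4 and 6 the lowest, 0.529%, 0.552% and 0.524%.

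Responses to obeticholic acid correlated between the lobes at r = 0.37 across genes, which are not independent replicates. If equal numbers are the same animal, differences between animals could give such a correlation with no effect of treatment. Splitting the 12 numbers at random gave a correlation as large in 32 of 100 splits (highest other 0.61, median 0.27), so it did not exceed what shared animals could give. The splits for signs and shared calls were chosen after those counts had been seen. The equal signs of called genes were reached by 41 of 100 splits for the non-embolized and 11 of 100 for the embolized lobe. The 3 genes called in both lobes were reached by 1 of 100, the real split (highest other 2); splits that mix the treatments can also call fewer genes, so a shared response to obeticholic acid stays a hypothesis.

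ENSOCUG00000024137, one of the genes that fell after obeticholic acid in the non-embolized lobe, was higher in obeticholic acid 3 and 6 than in the other treated libraries of each tissue, a pattern looked at after its values were seen. It was at 140 and 123 normalized counts in ileum against 19.9 to 33.2 in the other 4, at 71.1 and 71.8 in the non-embolized lobe against 5.90 to 11.6, and at 50.8 and 68.3 in the embolized lobe against 5.08 to 23.8. The same replicate numbers were thus high in each tissue. A single gene picked after its values were seen does not settle whether equal numbers are the same animal. Replicate numbers were not correlated between ileum and liver, so that pairing was not tested.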
